A study of Arabidopsis thaliana with 2 samples.

How the data were processed

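The series holds RNA-seq of Arabidopsis thaliana seedlings in duplicate; 2 libraries of 1 group (arp6-1 mutants at 17 °C, 15 min) were used here. Per the labels' protocols, total RNA was extracted from ground seedlings with a MagMAX kit, libraries were made with a stranded TruSeq kit and with an unstranded TruSeq kit, and paired-end reads were taken on a HiSeq2000 at the sequencing centres of the MPI in Tübingen and of BGI. The labels carry the same text for both libraries and do not say which library was made with which kit or read at which centre. The submitters' processing notes name FastQC, Trimmomatic, TopHat and Picard, without versions or roles, and the genome build TAIR10. The tool that counted reads and the strand setting are not given in the sources used here.

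Each deposited table lists 33557 genes with a locus and values in 3 units. The raw counts are whole numbers that the authors deposited without normalization, per the file headers. The FPKM column, per the file headers, holds the authors' fragments corrected for transcript length and library size. The authors' TPM column equals their FPKM rescaled to the same sum over all genes in each library, as a recalculation from the deposited values showed. In the files 4249 genes overlap another gene's span. A count of 0 beside a high FPKM in both libraries was found in genes with and without such an overlap, and its cause was not tested; the levels of such genes cannot be read from the counts.

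Levels were computed as TPM from the counts and the summed exon length of each gene in the annotation of TAIR10.1, the reference used here. Its gene models differ from those behind the files: 32810 of 33557 gene IDs matched (97.8%), and 43.7% of genes had the same start. Coordinates in the text are therefore those of the files, in TAIR10 per the submitters' notes, 1-based. No exon length was found for 755 genes, with 0.861% and 0.210% of the counts of replicates 1 and 2, and these stayed out of TPM. Computed and authors' TPM ranked genes alike (Spearman's rho across genes 0.975 and 0.973). Log levels are log2(TPM + 1).

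The depth was 20249142 counts in replicate 1 and 12410991 in replicate 2, and a count of 0 allows up to 3 counts, or 0.148 and 0.242 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3) over genes with at least 10 counts in both libraries, which gave factors of 1.02 and 0.976. The common dispersion came from an intercept-only edgeR fit. Each gene was tested between the libraries with the two-sided exact conditional binomial test, Benjamini-Hochberg adjusted, at a threshold of 0.05; it compares these libraries only. Ratios carry 95% Clopper-Pearson counting intervals. The count of genes was repeated with the edgeR exact test, the dispersion set to that of the reference genes.

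The 20 gene lists (263 genes), the tests and the rule for named genes were set before the data were examined. A list's level is the median over its members with a count in either library of the mean log2 level, given with the median in each library and its place among 10000 random lists of the same size. A list's difference is the median over tested members of the log2 difference of scaled CPM (prior count 2), with its place among 10000 random lists matched on expression in 20 bins. Lists beyond the central 95% of random lists, with equal tails, are called outside the range, which describes these libraries and is no p-value. Named were ARP6 and the reference genes, in each list the 2 highest and 2 lowest members and up to 4 differing members with the largest fold, the 20 highest genes, and the 10 genes with the largest difference each way among those past the test with a mean count of at least 50; examples in the text come mostly from this set, and other list members were added as examples after their values were seen. A further 6 lists (51 genes) were written after the data were seen and appear only in the closing part: abscisic acid receptors, clade A protein phosphatases, root hair, root endodermis and root stele genes, and DNA replication genes.

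The binomial test was tested on counts drawn with Poisson noise alone from the means and sizes of these libraries, so the result checks the computation and is no error rate for calls between the libraries, whose spread was larger: 85 of 100 genes changed 2-fold and 91 of 100 changed 4-fold were found among 19519, with 7 of 19319 unchanged genes called. Simulated coefficients of variation of 0.1 and 0.4 came back as 0.0996 and 0.397. Alternatives were size factors from DESeq2 1.42.0, total counts and nuclear genes only for the scaling, other count minimums, a pseudocount of 0.1, a prior count of 0.5, CPM in place of TPM, the mean over a list, and each replicate alone. Added after the data were seen were the authors' TPM, thinning of replicate 1 to the depth of replicate 2, and removal of a degree-3 polynomial trend on exon length and GC content. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. With 1 group there is no test between conditions and no split of samples to permute.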

Results

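Messenger RNA was profiled by RNA-seq in whole seedlings of Arabidopsis thaliana (accession Col-0) that carry the arp6-1 mutation. ARP6 is an actin-related subunit of the SWR1 complex, which puts the histone variant H2A.Z into nucleosomes in place of H2A. The seedlings were 10 days old, had been kept at 17 °C in long days, and belong to the 15 min time point of a temperature shift begun 1 h after dawn, in the arm that stayed at 17 °C. The labels give 1 group with 2 libraries, named replicate 1 and replicate 2. Replicate 1 held 20249142 counts over genes and replicate 2 held 12410991. At least 10 counts in both libraries were reached by 19519 of 33557 genes. No other genotype, temperature or time was analysed here, so levels are described within this group and the comparison is between its duplicates. Levels are in TPM, a transcript abundance corrected for gene length and library size that was computed from the counts, as mean ± SD of the 2 libraries (n = 2). The level of a gene list is the median over its members of their mean log2 levels, which is not the mean of the medians of the libraries, and those are given beside it. The labels do not say that the replicates came from separate cultures, so that the spread between them may be technical. Of the genes named here, ARP6, HTA3, HTA4, HTA9, HTA13, HSFA9, HSP101, GOLS1, CPHSC70-2, LNK2, WRKY40, WRKY53, PSBR and LEA7 have spans that overlap another gene in the files, so that their counts, levels and differences are uncertain.

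ARP6 (AT3G33520, chromosome 3, 14093656 to 14095549 in TAIR10) was close to absent, with 7 counts in replicate 1 and 7 in replicate 2. Its level was 0.514 ± 0.182 TPM, at percentile 0.201 of the 19433 genes with at least 10 counts in both libraries and a known exon length. ARP6 misses that minimum and is not among these genes, so a place near the bottom follows largely from the minimum. A count of 7 has an exact 95% Poisson interval of 2.81 to 14.4, which covers counting error only. The gene's span overlaps another gene in the files, so that its count is uncertain; the authors' own TPM values for it were also low, 0.339 and 0.560. The other SWR1 subunits were transcribed at ordinary levels. ARP4 stood at 41.0 ± 5.88 TPM, the helicase RVB1 at 36.1 ± 4.08 TPM, SWC4 at 16.9 ± 3.42 TPM and PIE1, the ATPase of the complex, at 13.8 ± 3.28 TPM. The paralogs RVB2B and YAF9B were near the bottom of the list at 1.09 ± 0.0617 and 1.31 ± 0.278 TPM. Over the list of 13 subunits the median was 3.87 (library medians 3.65 and 3.96) on the log2(TPM + 1) scale, inside the range that held the central 95% of 10000 random gene lists of the same size (the central range).

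Among the genes for H2A.Z, HTA9 was the main transcript at 195 ± 3.95 TPM. HTA11 had 80.2 and 20.8 TPM in replicates 1 and 2, HTA8 had 26 and 6.91 TPM, and HTA4, whose span overlaps another gene, was low at 3.40 ± 1.4 TPM. H2A.Z transcripts made up 22.6% of all H2A transcripts in replicate 1 and 30.8% in replicate 2 (26.7 ± 5.77, n = 2). HTA9 alone was 64.6% and 85.7% of the H2A.Z transcripts. Among the other H2A genes HTA10 had 254 and 100.1 TPM in replicates 1 and 2, HTA6 252 and 76.4 TPM and HTA5 142 and 112 TPM, and HTA12 was the least abundant in both libraries at 7.97 ± 0.862 TPM. Their median of 6.11 (library medians 6.56 and 5.66) lay above the central range of random lists, a call that was lost on the log2(CPM + 1) scale.

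Photosynthesis genes were the most abundant of the lists in both libraries. The list of light-harvesting and carbon-fixation genes had a median of 10.53 (library medians 10.56 and 10.54), above the central range, and took 4.1% and 3.77% of all TPM in replicates 1 and 2. RBCS1A, a small subunit of Rubisco, had the highest computed level of all genes in both libraries, 4150.0 ± 68.6 TPM. LHCB1.3, an antenna protein of photosystem II, stood at 3999 ± 12.2 TPM and the Rubisco activase RCA at 3903 ± 255 TPM. The photosystem proteins PSBR (2338 ± 364 TPM) and PSBO1 (2079 ± 13.8 TPM), the Calvin cycle enzymes GAPB (1778 ± 197 TPM) and FBA2 (1747 ± 91.2 TPM), and THI1 of thiamine synthesis (1763 ± 200.2 TPM) were also among the 20 genes with the highest mean. A ribosomal RNA gene, AT3G41768, was in that set as well, at 2817 and 960.0 TPM. LHCB4.3 was the lowest member of the photosynthesis list at 76.2 ± 22.1 TPM. The RBCS and LHCB1 genes are closely related copies, as are HSP90.2 to HSP90.4, BIP1 and BIP2, KIN1 and KIN2, COR15A and COR15B and the CBF genes. How reads were split among such copies is uncertain.

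**Figure D1:**
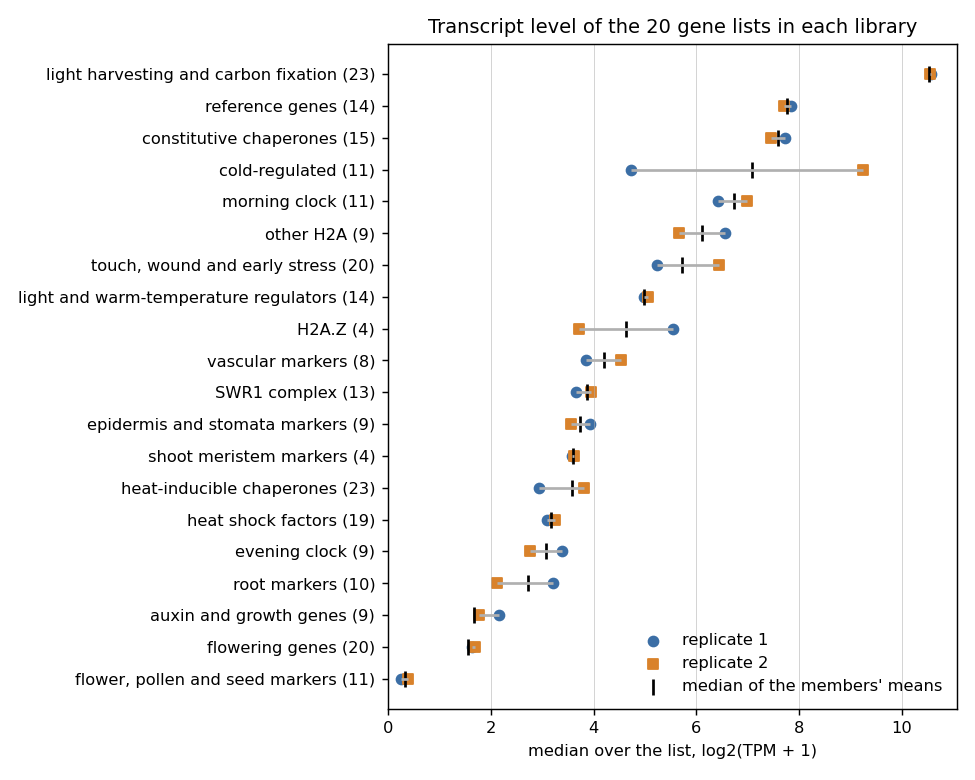
Median level of the 20 gene lists in each library on the log2(TPM + 1) scale, with the number of members that had a count in parentheses; circles are replicate 1, squares replicate 2, and the bar is the median of the members' mean log2 levels. The photosynthesis list stands highest at 10.53, the flower, pollen and seed list lowest at 0.33, and the cold-regulated list has the widest gap, from 4.72 in replicate 1 to 9.24 in replicate 2.

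The morning list of the circadian clock had a higher median than the evening list in both libraries. LHY reached 415 ± 18.0 TPM, CCA1 285 ± 100.4 TPM and the clock co-activators LNK2 and LNK1 274 ± 15.0 and 167 ± 66.6 TPM, while RVE6 and RVE7 stood at 27.8 ± 12.8 and 18.9 ± 5.46 TPM. Of the evening genes, GI stood at 27.9 ± 4.42 TPM, TOC1 at 18.7 ± 1.28 TPM, ELF4 at 7.63 ± 2.54 TPM, PRR3 at 1.05 ± 0.266 TPM and the photoperiod gene FKF1 at 0.179 ± 0.0724 TPM. GRP7, an RNA-binding protein with an evening peak, had 193 and 82.2 TPM in replicates 1 and 2. The median of the morning list exceeded that of the evening list by 3.63 ± 0.83 on the log2(TPM + 1) scale (n = 2), which is 12.4-fold in TPM + 1. With only genes of at least 10 counts in each library, the difference was 3.05. The median of the morning list was 6.73 (library medians 6.42 and 6.99), above the central range of random lists, and that of the evening list 3.08 (library medians 3.38 and 2.77), inside it.

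Heat-inducible chaperones were transcribed at low to moderate levels. The small heat shock proteins HSP17.6II and HSP23.6 stood at 1.84 ± 0.0672 and 0.914 ± 0.394 TPM, and the disaggregase HSP101 at 14.3 ± 1.17 TPM. HSP70-4 had 47.0 and 171 TPM in replicates 1 and 2 and the galactinol synthase GOLS1 25.6 and 52.3 TPM. The list's median was 3.58 (library medians 2.94 and 3.81), inside the central range of random lists, and so was that of the heat shock factors, 3.18 (library medians 3.09 and 3.25). HSFA4A had 23.7 and 91.8 TPM in replicates 1 and 2, and HSFA9, known from seeds, had a count of 0 in both libraries, which allows at most 0.148 and 0.242 CPM (counts scaled to library size). HSFB1 also had 0 counts, although the authors' TPM for it was 54.1 and 72.0, so that its level cannot be read from the counts. Constitutive chaperones were far more abundant, with a median of 7.59 (library medians 7.72 and 7.45), above the central range, with HSC70-1 at 1242 ± 11.8 TPM and HSP90.3 at 329.7 ± 72.1 TPM.

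Regulators of light and warm-temperature growth were moderately transcribed. PIF5 stood at 91.9 ± 35.2 TPM, HY5 at 78.0 ± 26.8 TPM, the photoreceptor gene PHYB at 61.8 ± 1.87 TPM and PIF4 at 15.5 ± 7.14 TPM, and the list's median of 4.99 (library medians 4.99 and 5.06) fell just inside the central range of random lists; it passed the range with CPM or with the authors' TPM. Growth-associated auxin genes were low, with IAA29 at 0.368 ± 0.245 TPM, SAUR22 at 0.483 ± 0.368 TPM and TAA1, which makes the auxin precursor, at 15.4 ± 4.54 TPM. Their list median was 1.68 (library medians 2.16 and 1.77), inside the central range, and below it with the mean over the list. Flowering genes had a median of 1.56 (library medians 1.64 and 1.69), below the central range. The repressor SVP stood at 29.6 ± 4.61 TPM, FLC at 7.79 ± 4.13 TPM, the florigen FT at 2.34 ± 0.684 TPM and the floral identity gene AP1 at 0.0637 ± 0.0225 TPM, while SOC1 had 20.2 and 76.7 TPM in replicates 1 and 2. FLM was 16.6 ± 2.2 TPM from counts and 55.9 and 70.3 in the authors' TPM, so that its level is uncertain.

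Markers of shoot and root tissues were detected, and those of flowers, pollen and seeds were near 0. The epidermal genes PDF1 and FDH stood at 464 ± 81.8 and 310.1 ± 74.8 TPM, the stomatal lineage gene MUTE at 2.52 ± 0.814 TPM, and the list's median was 3.75 (library medians 3.93 and 3.57). For vascular tissue, the phloem sucrose transporter SUC2 had 70.6 and 181 TPM and the xylem protease XCP2 70.9 ± 16.4 TPM, and the list's median was 4.2 (library medians 3.85 and 4.54). Shoot meristem genes were represented by CLV1 at 32.8 ± 4.27 TPM and KNAT1 at 22.0 ± 0.541 TPM, with 0 counts for WUS and a list median of 3.60 (library medians 3.59 and 3.61). Root markers had a median of 2.72 (library medians 3.21 and 2.13), with SCR highest at 65.9 and 54.1 TPM in replicates 1 and 2, PIN2 at 18.5 and 6.42 TPM, and PLT1 and PLT2 at 0.809 ± 0.398 and 0.996 ± 0.271 TPM. These lists lay inside the central range. Flower, pollen and seed markers had a median of 0.33 (library medians 0.25 and 0.40), below the central range: AG, VGD1, CRU3 and LEC1 had 0 counts in both libraries, while the seed genes EM6 and EM1 had 0.578 and 27.4 TPM and 0.540 and 15.0 TPM. The call for this list was lost when only genes with at least 10 counts in each library were kept. The reference genes had a median of 7.77 (library medians 7.85 and 7.71), above the central range, with GAPC2 at 1380.0 ± 125 TPM and TIP41 at 38.1 ± 0.336 TPM.

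The genes with the largest differences between the duplicates were higher in replicate 2. LEA7 and RAB18 (AT5G66400), proteins that accumulate in drying tissue, had 2.03 and 3.06 TPM in replicate 1 against 1699 and 1693 TPM in replicate 2, 862-fold and 569-fold (95% counting intervals 9.15 to 10.43 and 8.71 to 9.64 on the log2 scale). LTI65, also known as RD29B and induced by abscisic acid, was 407-fold higher, the stress-induced membrane protein TSPO 189-fold, LEA4-5 185-fold and HAI3, a protein phosphatase of abscisic acid signalling, 160.1-fold. The remaining genes among the 10 with the greatest rise were AT3G56275 (512-fold), a transcribed pseudogene in the annotation, AT5G15500 (333-fold), AT3G02480 (174-fold) and AT2G37870 (158-fold). Lower in replicate 2 were NEET, an iron-sulfur protein (28.7-fold), the receptor-like kinase CRK30 (19.7-fold), AZI1 (17.1-fold), RL4 (16.3-fold) and the glutathione transferase GSTF14 (11.5-fold). AT1G05250 and AT1G05240, a near-identical pair of peroxidase genes whose reads may be split between them, were 14.6-fold and 14.3-fold lower, AT3G16670 12.2-fold, the chloroplast gene ATCG01100 11.3-fold and AT2G43140 11-fold. NEET lies on chromosome 5 at 21009592 to 21010345 and LEA7 on chromosome 1 at 19619745 to 19621534 in TAIR10. For the lists, members past the exact binomial test on the counts, which covers counting error only, are given first. Those past the edgeR exact test with the dispersion of the reference genes (the reference spread) follow. The reference spread came from these same libraries and was smaller than that over all tested genes (coefficient of variation 13.6% against 38.8%). Calls with it do not allow for the full spread between the duplicates. Of all 19519 tested genes 63.8% passed the binomial test, and 4422 passed with the reference spread. A list whose count of members is near these shares is not set apart by it. Chloroplast genes held 0.777% of counts in replicate 1 (exact 95% interval 0.773 to 0.781) and 0.179% in replicate 2 (0.177 to 0.181), and ribosomal RNA genes 0.535% (0.532 to 0.538) and 0.180% (0.178 to 0.183).

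**Figure D2:**
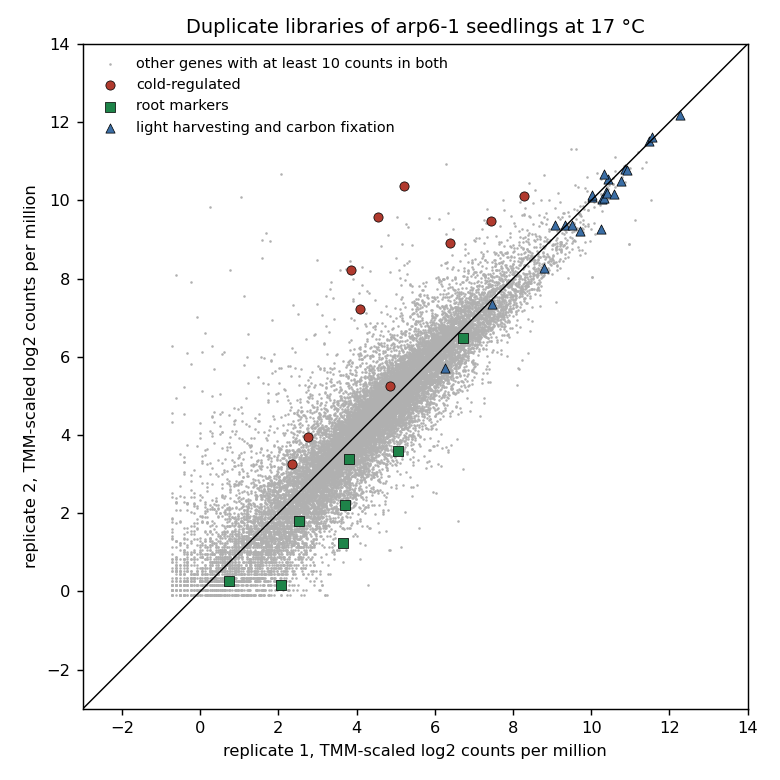
Each point is a gene with at least 10 counts in both libraries, at its TMM-scaled log2 CPM in replicate 1 (x axis) and replicate 2 (y axis); the line marks equal values. Cold-regulated genes (red circles, median difference 2.28) lie above the line, root markers (green squares, -1.1) below it, and photosynthesis genes (blue triangles, -0.14) close to it.

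Cold-regulated genes were higher in replicate 2 as a group. Of 10 tested members, 10 were higher and 0 lower (9 higher and 0 lower with the reference spread), with a median log2 difference of 2.28 (4.87-fold; SD of members 1.72), above all 10000 random lists matched on expression. RD29A had 23.9 and 840.2 TPM in replicates 1 and 2, COR15A 25.4 and 812 TPM and KIN1 29.8 and 602 TPM, all genes that also answer to dehydration and abscisic acid. Their log2 differences were 5.18 (95% counting interval 5.07 to 5.28), 5.04 (4.91 to 5.17) and 4.37 (4.2 to 4.55). The cold regulators CBF1, CBF2 and CBF3 differed less, by 2.3-fold, 1.31-fold and 1.90-fold. COR413 and KIN2 had 277 and 1108 TPM and 194 and 1087 TPM. The list's level of 7.09 (library medians 4.72 and 9.24) rested on replicate 2: replicate 1 alone lay inside the central range of random lists.

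Early stress genes and heat-inducible chaperones were also higher in replicate 2. In the touch, wound and early stress list, 16 of 20 genes were higher and 2 lower (12 higher and 0 lower with the reference spread; median log2 difference 0.87), among them the transcription factors WRKY53 (4.27-fold), WRKY40 (4.06-fold) and ZAT12 (3.21-fold), and JAZ5 (3.03-fold); SZF1 and TCH4 stood at 339.5 ± 136 and 307 ± 121 TPM, and the level of the list, 5.72 (library medians 5.23 and 6.43), was above the central range. Of 19 tested members of the heat-inducible chaperone list, 12 were higher and 1 lower (9 higher and 0 lower with the reference spread, median 0.79). The higher members include genes that are no chaperones, such as DREB2A and GOLS1. HSP21 was 7.65-fold, HSP17.6A 6.08-fold, HSA32 5.39-fold and HSP70-4 3.74-fold higher, and the co-chaperone ROF2 was 2.38-fold lower. HSP22 had 0 and 47 counts, at least 26.9-fold higher in replicate 2 against a floor of 3 counts. Of 16 heat shock factors 6 were higher and 4 lower by the binomial test, and 3 higher and 0 lower with the reference spread. HSFA4A was 3.98-fold and HSFA1E 2.54-fold higher, HSFA3 1.83-fold lower, and HSFA6A had 0 against 211 counts (at least 121-fold). Their median of 0.35 passed the range of matched lists, but not with the mean over the list, with a minimum of 50 counts or after removal of a length and GC trend. Of 15 constitutive chaperones 14 were lower and 0 higher by the binomial test, but 2 were lower and 0 higher with the reference spread, with HSP90.6 2.23-fold and the plastid protein CPHSC70-2 1.89-fold lower; their median of -0.38 stayed inside the range and passed it with the mean.

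Morning clock genes were higher in replicate 2, 10 of 11 against 1 lower (6 higher and 0 lower with the reference spread), with a median of 0.77; RVE1 was 3.20-fold and RVE2 2.57-fold higher, while LHY differed by 1.09-fold and RVE7 was 1.47-fold lower. Evening genes went both ways, 2 higher, 3 lower and 3 not past the test of 8 (0 higher and 1 lower with the reference spread; median -0.05), with GRP7 2.28-fold lower and BOA 1.55-fold higher. Of 14 light and warm-temperature regulators 11 were higher and 1 lower (4 higher and 0 lower with the reference spread; median 0.37), with PIF3 5.24-fold, ATHB2 2.68-fold and PIF4 2.02-fold higher and HY5 1.60-fold lower; this median lay inside the range of matched lists, and outside it with the mean or after the length and GC trend was removed. Among flowering genes, 5 of 14 were higher and 2 lower (4 higher and 0 lower with the reference spread), with FUL 5.83-fold, SPL4 5.31-fold, SOC1 3.91-fold and FLC 2.26-fold higher. Their median of 0.21 lay inside the range; it was 0.58, above the range, with the mean, 0.04 with a minimum of 50 counts and close to 0 after the trend was removed. Auxin and growth genes had 0 higher and 3 lower of 6 (0 higher and 1 lower with the reference spread; median -0.42, inside the range, and -0.09 over genes with a count in either library); YUC2, an auxin biosynthesis gene, was 2.63-fold and XTR7 1.80-fold lower.

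Root markers and histone H2A genes were lower in replicate 2. Of 8 tested root markers, 7 were lower, 0 higher and 1 did not pass the test (0 higher and 4 lower with the reference spread), with a median of -1.1 (2.14-fold lower; SD of members 0.79), below the range of matched lists. The root hair expansin EXPA7 was 5.55-fold lower (log2 difference -2.47, 95% counting interval -3.10 to -1.90), the epidermal regulator WER 4.08-fold, COBL9 2.86-fold and the auxin carrier PIN2 2.81-fold, whereas SCR was 1.18-fold lower. HTA8 and HTA11 were 3.66-fold and 3.75-fold lower (log2 differences -1.87, -2.37 to -1.41, and -1.91, -2.16 to -1.66), while HTA9, with a counting interval of -0.11 to 0.10, and HTA4 did not pass the test. Among the other H2A genes 7 of 9 were lower and 0 higher (0 higher and 5 lower with the reference spread; median -0.87), with HTA6 3.20-fold, HTA13 2.62-fold, HTA10 2.46-fold and HTA3 2.44-fold lower; the H2A.Z genes had 0 higher and 2 lower of 4 (0 higher and 2 lower with the reference spread) and a median of -0.92, and both H2A lists lay below the range. SWR1 subunits had 1 gene higher and 5 lower of 12 tested by the binomial test, and 0 higher and 0 lower with the reference spread; by the binomial test only, PIE1 was 1.44-fold higher and SWC5 1.46-fold lower, and the median of -0.19 lay inside the range.

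Other tissue markers differed in part. Of 8 vascular markers 6 were higher in replicate 2 and 0 lower (3 higher and 0 lower with the reference spread; median 0.58, above the range, inside it with the mean), with SUC2 2.64-fold and the phloem regulator APL 1.96-fold higher. Epidermis and stomata markers split into 4 higher and 4 lower of 9 (1 higher and 1 lower with the reference spread; median 0.40, inside the range, and 0.07 with the mean); CER6, an enzyme of wax synthesis, was 2.08-fold higher and the stomatal signal EPF2 3.10-fold lower. In the shoot meristem list 1 of 3 genes, CLV1, was lower (1.17-fold) and 0 were higher (0 higher and 0 lower with the reference spread), and the median was -0.01. The only tested member of the flower, pollen and seed list, SEP3, was 3.13-fold lower, by both tests. It does not stand for that list. Its 2 highest members were outside the test and higher in replicate 2: EM6 (0.578 and 27.4 TPM in replicates 1 and 2) and EM1 (0.540 and 15.0 TPM). Of 23 photosynthesis genes 8 were higher and 15 lower by the binomial test, while with the reference spread 0 were higher and 1 lower, RBCS1B (1.98-fold); their median was -0.14, and -0.05 after the trend was removed. The reference genes had 3 higher, 7 lower and 4 not past the test of 14 by the binomial test, a median of -0.08 and UBQ5 1.53-fold lower. Of the 19 lists with a median, 6 lay above and 3 below the range of matched lists. Scaling by total counts shifted all log2 differences alike by -0.07, and the other scalings by less. The number of members past the binomial test was the same adjusted over the list alone in 18 of 20 lists; it was 5 for the SWR1 complex and 11 for the reference genes.

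**Figure D3:**
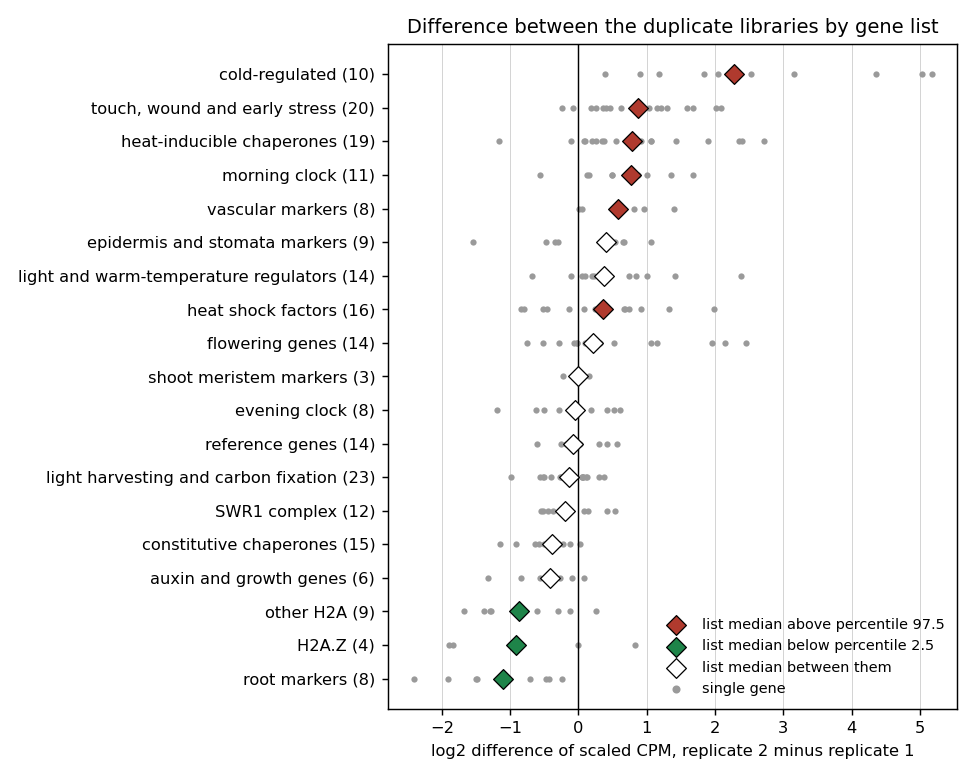
Log2 difference of scaled CPM, replicate 2 minus replicate 1, for each tested gene (grey points) and the median (diamond) of each list, with the number of tested genes in parentheses. Red diamonds lie above and green ones below the central 95% of random lists matched on expression; the medians run from -1.1 for root markers to 2.28 for cold-regulated genes.

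Over all 19519 tested genes, 12452 (63.8%) differed by the exact binomial test on the counts with Benjamini-Hochberg adjustment, 6220 higher and 6232 lower in replicate 2. With the edgeR exact test and the reference spread (a coefficient of variation of 13.6%) the count was 4422, 2236 higher and 2186 lower. Of the list members named above as higher or lower, CBF2, ROF2, HSFA3, RVE7, LHY, BOA, HY5, XTR7, SCR, PIE1, SWC5, CLV1 and UBQ5 passed the binomial test only. More than 4-fold differences were seen for 463 genes higher and 210 lower, and more than 16-fold for 75 and 4. A further 62 genes had under 10 counts in replicate 1 and at least 50 in replicate 2, and 114 the reverse, all outside the test. These limits are on raw counts, and replicate 1 was the deeper library, so that the reverse was met at a smaller fold. The numbers therefore do not show more genes lost than gained in replicate 2. Across the tested genes, which are not independent replicates, log2 levels correlated with Pearson's r = 0.912 and Spearman's rho = 0.919, the median absolute difference was 1.35-fold and the common biological coefficient of variation was 38.8%. Chi-square over degrees of freedom was 109, so the libraries were not a single library deposited again. The 20 genes with most counts took 4.76% (4.75 to 4.77) and 4.3% (4.29 to 4.31). The tests compare these 2 libraries only and no condition, since each side is a single library.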

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

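The tests in this part were chosen after the data were seen. Signal stood in a column that the comparisons do not use: 88 genes had 0 counts in both libraries and an authors' TPM above 10 in both. A count of 0 allows 0.148 and 0.242 CPM, which is not corrected for gene length and so is not on the scale of TPM. The span of 64 of these genes overlaps that of another gene, against 4249 of all 33557 genes. The highest was the metallothionein gene MT1A (AT1G07600, chromosome 1, 2338904 to 2339321), with a mean authors' TPM of 1877 (1094 in replicate 1 and 2659.6 in replicate 2). AT3G02468 followed with a mean of 883, AT1G70782 with 347, the homeobox gene HB-1 with 232 and AT2G47115 with 202. Of these 5 genes AT1G70782 alone is listed without an overlap; AT1G70780, which the reference annotation places at the same position, was not analysed here, and which of the pair the value belongs to is open. Levels of such genes cannot be read from the counts.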

How the results depend on the processing

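The authors' TPM, the thinning and the length and GC trend were chosen after the data were seen; all other alternatives were planned. Genes differing between the duplicates numbered 4422 with the edgeR exact test and the reference genes' dispersion (2236 higher, 2186 lower), against 12452. That test adds spread beyond counting noise, which lowers the count by construction. The added spread came from the same libraries, with a coefficient of variation of 13.6% against 38.8% over all tested genes. The count of 4422 thus does not allow for the full spread between the duplicates. Other scalings, minimums and thinning gave 10788 to 13082, and the share of calls higher in replicate 2 was 43.7% with total counts as scaling. The coefficient of variation of 0.388 became 0.440 without a filter and 0.346 at 50 counts, since low counts enter or leave. The ARP6 level of 0.59 on the log2 scale became -0.74 with a pseudocount of 0.1, because a TPM under 1 has a log near or below 0, and no value came from the minimum of 10 counts, which ARP6 misses. Each replicate alone gave a clock difference of 3.04 and 4.22 and an H2A.Z share of 22.6 and 30.8%, which with n = 2 says nothing about stability. Of single list levels, 134 values over the alternatives kept their place inside or outside the central range, 3 entered it and 3 left it; of list differences 144, 4 and 4, with none crossing to the other side of the range. Medians inside the range changed sign for the flowering genes with the trend removed, the evening clock with thinning and the shoot meristem with a count in either library. No paired analysis was possible because there is 1 group. Depth limits genes such as ARP6, with 7 counts per library.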

Other observations

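The 6 gene lists in this part were written after the data were seen, and the tests of counting, of kit and centre and of abscisic acid signalling were chosen after the results they bear on were seen in part, as thinning and the length and GC trend were after the data were seen. By the binomial test, the tested phosphatases and most of the tested receptors of abscisic acid signalling differed in opposite directions between the duplicates. Of the 9 clade A protein phosphatases, which restrain the signal and are induced by it, 7 had counts enough for the test, 7 were higher in replicate 2 and 0 lower (7 higher and 0 lower with the reference spread): HAI1 151-fold, AHG3 11.7-fold, ABI2 10.1-fold and ABI1 3.87-fold (median log2 difference 3.32, above the range of matched lists). HAI2 had 2 and 571 counts, a log2 ratio of 8.93 with a 95% counting interval of 7.08 to 11.98. Of 8 tested abscisic acid receptors 6 were lower and 1 higher (1 higher and 4 lower with the reference spread; median -0.89, below the range), with PYL4 6.91-fold and PYL1 2.64-fold lower and PYL7 3.43-fold higher.

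The medians of the root hair, endodermis and stele lists differed in size, while single members overlapped between the lists. All 9 tested root hair genes were lower in replicate 2 (6 with the reference spread; median -1.91), with PRP3 5.84-fold, RSL2 4.67-fold and EXPA18 4.2-fold, and CSLD3 1.15-fold. Of 4 tested endodermis genes 3 were lower (3 with the reference spread; median -1.36), among them CASP1 2.78-fold and MYB36 4.12-fold. Of 4 stele genes 2 were lower (1 with the reference spread; median -0.39, inside the range of matched lists), with NPF7.3 2.84-fold and PHO1 1.49-fold, while SKOR and HKT1 did not pass the test. All 8 DNA replication genes were lower by both tests, PCNA2 4.04-fold, MCM7 3.02-fold and MCM5 2.01-fold. PYL7, CASP1, SKOR, PCNA2 and MCM7 overlap other genes in the files and are uncertain.

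The cold-regulated genes were higher in replicate 2, with a median log2 difference of 2.28. A length or GC bias is argued against by a median of 2.28 after removal of the trend, which held 1.05% of the variance. After replicate 1 was thinned, the median was 2.26. Thinning lowers counts and library size alike, and the 10 tested members had at least 50 counts in both libraries. The median was thus bound to change little, and no conclusion on unequal depth is drawn from it. The median from the authors' TPM departed from that of the counts by 9.38e-05, so the difference is not particular to the raw counts. Both units describe the same reads of each library. An alignment or strand setting that differed between the libraries could move both alike. Such a setting would act on genes in general, not on this list alone. The reference genes had a median of -0.08 (SD of members 0.29) and the photosynthesis genes one of -0.14 (SD 0.30). All 10 tested cold-regulated members were higher, and their spans overlap no other gene in the files. These values argue against different counting as the cause of the list's median difference. A part in single members stays open. The library kit, sequencing centre or day cannot be told apart from the replicate, since the labels hold 1 protocol text for both libraries. An abscisic acid response in the seedlings of replicate 2 is a candidate explanation: the 5 tested phosphatases whose values had not been seen when it was written had a median of 2.82 (SD 0.72), while 7 such receptors had one of -0.82 (SD 1.1), less than their spread. The design gives no treatment or group that would test it.

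For the root markers that were lower in replicate 2, a length or GC bias is argued against by a median of -1.07 after the trend was removed. A smaller share of root tissue alone would lower genes transcribed only in roots alike. The medians of the root hair, endodermis and stele lists spanned 1.52 log2 units (bootstrap SD over members 0.47). A span of medians is positive through scatter alone, so this SD is no measure of how unlike the lists are. The span of 1.52 was over the 1 unit set before those lists were computed. The span passed that limit through the stele list (-0.39), as the root hair (-1.91) and endodermis (-1.36) medians lay within 1 unit of each other. The stele list has 4 tested genes and some of them, such as HKT1, are also transcribed in shoots. The span therefore cannot decide the question. A smaller root share, as the whole or part of the cause, stays open. The root hair and endodermis lists both lay below the range of matched lists. The endodermis median of -1.36 argues against a change within root hairs as the whole cause, and such a change as a part of it stays open. No biological explanation given by the design was tested.

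For the H2A genes that were lower in replicate 2, a length or GC bias is argued against by a median of -0.76 for the other H2A genes after the trend was removed. Less DNA replication in the tissue of replicate 2 is a candidate explanation: the MCM and PCNA genes had a median of -1.42, below the range of matched lists, and this could have come out otherwise. HTA9, with a counting interval of -0.11 to 0.10 around its log2 difference, did not follow HTA8 and HTA11. Whether fewer dividing cells were sampled, as a smaller share of root tips might give, or division slowed was not tested.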
